A study of Mus musculus with 12 samples.

How the data were processed

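Small RNA from the livers of 12 C57BL/6 mice with carbon tetrachloride (CCl4) injury was sequenced, 1 library per mouse, per the labels. RNA was extracted with Trizol and libraries were made with the TruSeq Small RNA kit. Of these mice, 6 were given PZH (Pien Tze Huang, a traditional Chinese medicine) by the intragastric route and 6 were given double distilled water. The series holds no healthy mice, so every comparison lies within CCl4-treated animals.

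The deposited table gives raw counts for 1929 mature mouse miRNAs in the 12 libraries, with no normalization. The submitters' notes name cutadapt, FastQC, BWA, DESeq2 and the genome build GRCm38, without versions, settings or order. The counting tool, the miRNA annotation release, the use of strand and the handling of reads that match several miRNAs are not given in the sources used here. Values of near-identical miRNAs, such as members of the let-7, miR-29, miR-30, miR-200 and miR-17 families, therefore carry an unknown share of reads from their relatives. No cell of the table held the value 1, while 3049 cells held 2 and 6775 held 0. This was seen from the values alone, and it means that detection in the table as deposited stands for 2 or more counts. Total counts ranged from 4961913 to 20211784 per library. All 12 libraries were used and none was pooled. No labels give a sequencing date or batch. The reads carry no molecular identifiers. The SDs given are spreads between mice. The SEs of log2 fold changes were derived from the edgeR test statistic, which shares information on variance across miRNAs.

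The design, the tests, 17 miRNA lists and the rule for naming miRNAs were fixed before the data were examined. Counts were compared between PZH and water with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after TMM scaling and the default filter on low counts, which kept 607 miRNAs. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are PZH against water on the log2 scale, and levels are CPM after TMM scaling. Replicate numbers 1 to 6 occur in both groups, but no source says that they pair mice, so no pairing was used. The correlation of same-numbered libraries, after centring on group means, lay between -0.15 and 0.08. Of the water libraries, only replicate 1 correlated best with the PZH library of its own number.

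The fixed lists stood for cell types and tissues (hepatocyte, mesenchymal, leukocyte, endothelial, erythroid, epithelial and biliary, pancreas, muscle and neural), for roles in fibrosis (promoting and restraining), for miRNA families and clusters (miR-17-92 and paralogs, let-7, p53 and miR-34, Dlk1-Dio3), and for lipid metabolism and hypoxia. They held 162 names, of which miR-199a-3p and miR-486a-5p were not in the table. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with a correlation estimated from the data. The fry test was run beside them. It asks whether the members of a list move, on balance, in 1 direction, and its mixed form asks whether they change in either direction. Neither form compares the list with other miRNAs. The 14 tested lists form 1 family for adjustment. Some miRNAs stand in several lists. Of the fibrosis-restraining list, 9 members stand in other lists too, and of the hepatocyte list 4.

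Library composition was compared with two-sided exact permutation tests over the 924 assignments of libraries to groups. The separation of whole profiles was tested over the 462 splits into 6 and 6, as the percent of the summed squared distance between log2 CPM profiles (prior count 2) that lay between groups. The ratio of the 5p to the 3p arm of a hairpin was compared with limma on log2 counts with a pseudocount of 1, where both arms had a mean of at least 20 counts. Positions come from the GRCm38 annotation, in which 1841 of the names had a single hairpin position.

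The rule named the 12 largest increases and the 12 largest decreases among called miRNAs with a mean of at least 10 CPM, the 10 most abundant miRNAs, and up to 4 members with the smallest p of each list. It named 82 miRNAs. Any other miRNA in the text was chosen after its values were seen, and so were the exact tests of list means, the tests of genomic regions and the count of miRNAs named without an arm.

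The method was tested on simulated data with known changes. Recovery was counted among changed miRNAs that passed the filter. It was 20.8% of 48 changes of 1.25-fold, 61.2% of 49 of 1.5-fold, 82.0% of 50 of 2-fold and 100% of 43 of 4-fold. Of the calls, 3.88% were false. Counts were simulated with no correlation between miRNAs, so the share of false calls in real data can differ. With no simulated change the median number of calls was 0. For arm ratios, 18 of 20 simulated changes of 2-fold were recovered, with 0 false calls.

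Alternatives were RLE, TMMwsp and total-count scaling, no filter, a filter of 10 CPM in 6 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, robust edgeR, a block for the replicate number, thresholds of 0.1 on adjusted p and of 1 on log2 fold change, other arm minimums and pseudocounts, and each library left out in turn. After the data were seen, 2 more were added: thinning every library at random to the smallest total, and leaving out names that lack an arm. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.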

Results

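Liver miRNAs were measured in 12 mice with liver injury by CCl4, a toxin given by intraperitoneal injection to produce hepatic fibrosis. The 6 mice of the water group and the 6 of the PZH group differed by the labels only in what they were given by the intragastric route. Total counts in the water group were 14556735, 20211784, 7947714, 9386001, 11044980 and 4961913 for replicates 1 to 6. In the PZH group they were 6065480, 8452845, 10436478, 9877693, 8249401 and 8848912. The means were 11.4 ± 5.39 M and 8.66 ± 1.52 M counts (SD, n = 6 each; two-sided exact permutation p = 0.29).

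The most abundant miRNA in all 12 libraries was miR-21a-5p, which is induced in injured liver. It held 18.8% ± 0.947 of counts with water and 19.1% ± 1.14 with PZH (SD, n = 6; exact permutation p = 0.556). The hepatocyte miRNA miR-122-5p stood at 104137 ± 8000 CPM with water and 107905 ± 13911 CPM with PZH (SD, n = 6). The 10 most abundant miRNAs held 60.8% and 60.9% of counts (exact permutation p = 0.848). The number of miRNAs detected was 1434 ± 203 with water and 1295 ± 48.0 with PZH (SD, n = 6; exact permutation p = 0.134), and after every library was thinned to the smallest total it was 1328 and 1239 (exact permutation p = 0.134). Thinned libraries can hold single counts, which were taken as detected. Water replicate 6, the smallest, was left as it was and held none. Thinning therefore corrected for depth only in part. Without water replicate 6, the library with the lowest total, the difference was -203 before thinning, with no correction for depth (exact permutation p = 0.00649), and -132 after it (exact permutation p = 0.0108). With any other library left out, the exact permutation p after thinning lay between 0.108 and 0.258.

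Whole miRNA profiles of the PZH livers stood apart from those of the water livers. Of the summed squared distance between profiles, 40.1% lay between the groups, against 27.2% at most in any other split of the 12 libraries into 6 and 6 (exact permutation p = 0.00216, the smallest that this test can give). The first principal component carried 42.7% of the variance and the second 9.58%. Correlations across miRNAs lay between 0.984 and 0.991 within the water group, between 0.981 and 0.991 within the PZH group, and between 0.964 and 0.983 across groups; miRNAs are not independent replicates.

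**Figure D1:**
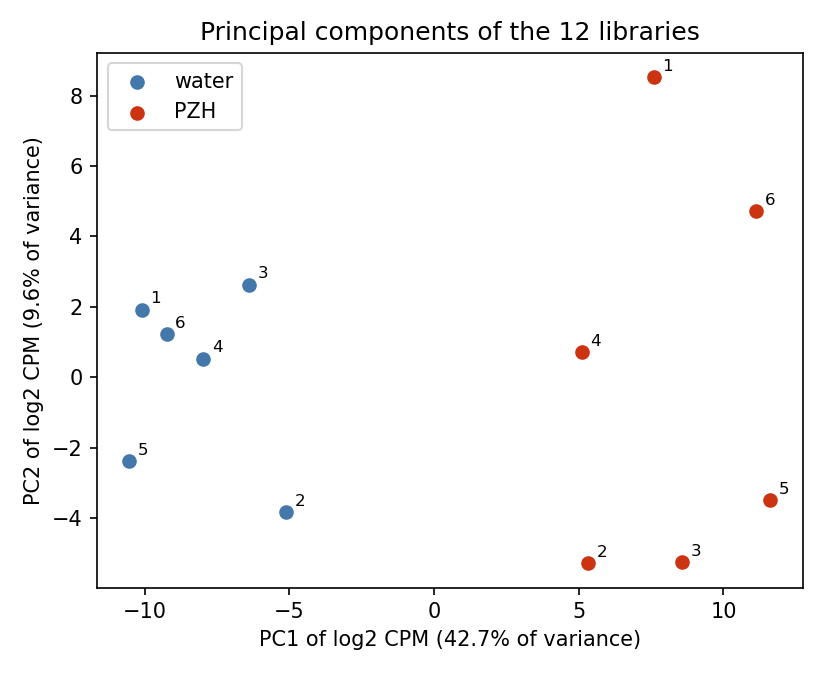
Scores of the 12 libraries on the first 2 principal components of log2 CPM over 607 tested miRNAs, with 1 point per mouse labelled by replicate number. The first component carries 42.7% of the variance and the second 9.58%.

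The central question was which miRNAs differ between injured livers of mice given PZH and those given water. With PZH, miRNAs of the imprinted Dlk1-Dio3 region of chromosome 12 were higher, among them miR-541-5p at 3.04-fold. Among miRNAs with a mean of at least 10 CPM, the largest decreases included those of miR-6356, 16.4-fold lower, and miR-2137, 8.29-fold lower. Several miRNAs linked to restraint of fibrosis, such as miR-30a-5p and miR-29c-3p, were modestly lower. The most abundant miRNAs of the liver, miR-21a-5p and miR-122-5p, differed by less than the spread between mice.

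Of 607 tested miRNAs, edgeR called 129, of which 60 were higher and 69 lower with PZH. At an unadjusted p under 0.05 there were 196. The absolute log2 fold change had a median of 0.90 among called miRNAs, and it was at least 1 in the direction of increase for 35 and of decrease for 23. The groups did not overlap at all for 61 of the 607 tested miRNAs, 60 of them called, where chance gives 0.216% of the miRNAs tested. The median log2 fold change of all tested miRNAs was -0.03.

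**Figure D2:**
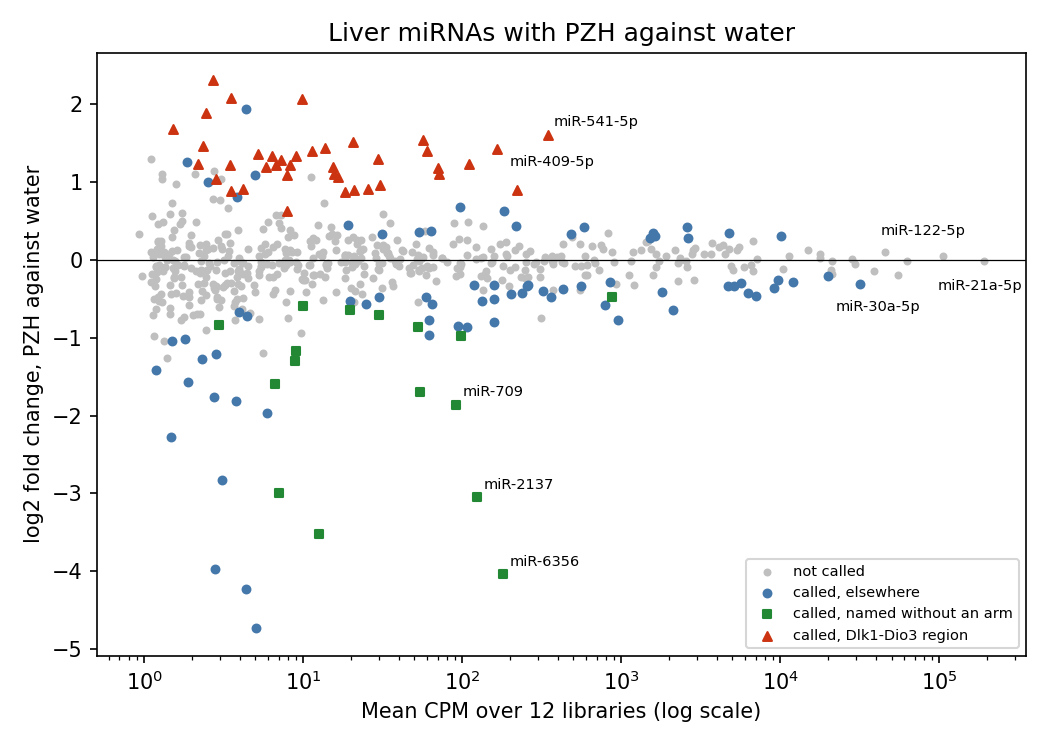
Log2 fold change of PZH against water plotted against mean CPM on a log axis for 607 tested miRNAs, with 1 point per miRNA and called ones in colour by kind (Dlk1-Dio3 region, named without an arm, elsewhere). The 60 higher and 69 lower calls spread over the range of abundance, with miR-6356 and miR-2137 among the largest decreases.

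Among the 12 largest increases of miRNAs with a mean of at least 10 CPM, miR-541-5p went from 170 ± 43.4 to 518 ± 154 CPM (SD, n = 6; log2 fold change 1.60, SE 0.21, edgeR adjusted p = 5.90e-05). Its hairpin lies on chromosome 12 from 109742409 to 109742498, in an intron of the non-coding gene Mirg. The level of miR-409-5p went from 89.4 ± 19.1 to 240 ± 58.4 CPM (SD, n = 6; log2 fold change 1.42, edgeR adjusted p = 2.71e-05). The others were miR-377-3p (log2 fold change 1.54), miR-1193-3p (1.51), miR-409-3p (1.44), miR-411-3p (1.40), miR-434-5p (1.40), miR-337-5p (1.30), miR-379-5p (1.23), miR-154-3p (1.19), miR-134-5p (1.18) and miR-127-3p (1.11). For 11 of the 12, each of the 6 PZH mice was above every water mouse, and for miR-127-3p this held for 5 of 6.

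All 12 come from the Dlk1-Dio3 region, whose miRNAs are processed from non-coding RNAs expressed from the maternal chromosome. The fixed list for this region had 22 tested members, of which 15 rose (18 rose when adjusted over the list alone). Its median log2 fold change was 1.10, and all 22 members had positive values under each scaling tried. By camera the list was higher than other miRNAs (adjusted p = 5.95e-13), a call not kept with a correlation estimated from the data (adjusted p = 0.495 with an estimated correlation). By fry its members moved up on balance (adjusted p = 0.00372). The member with a role in lipid metabolism, miR-370-3p, rose from 3.75 ± 1.75 to 15.9 ± 4.86 CPM (SD, n = 6; log2 fold change 2.06, edgeR adjusted p = 0.000133). Water replicate 2 had the highest level of miR-379-5p among water libraries, 95.7 CPM against 64.2 in the next.

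**Figure D3:**
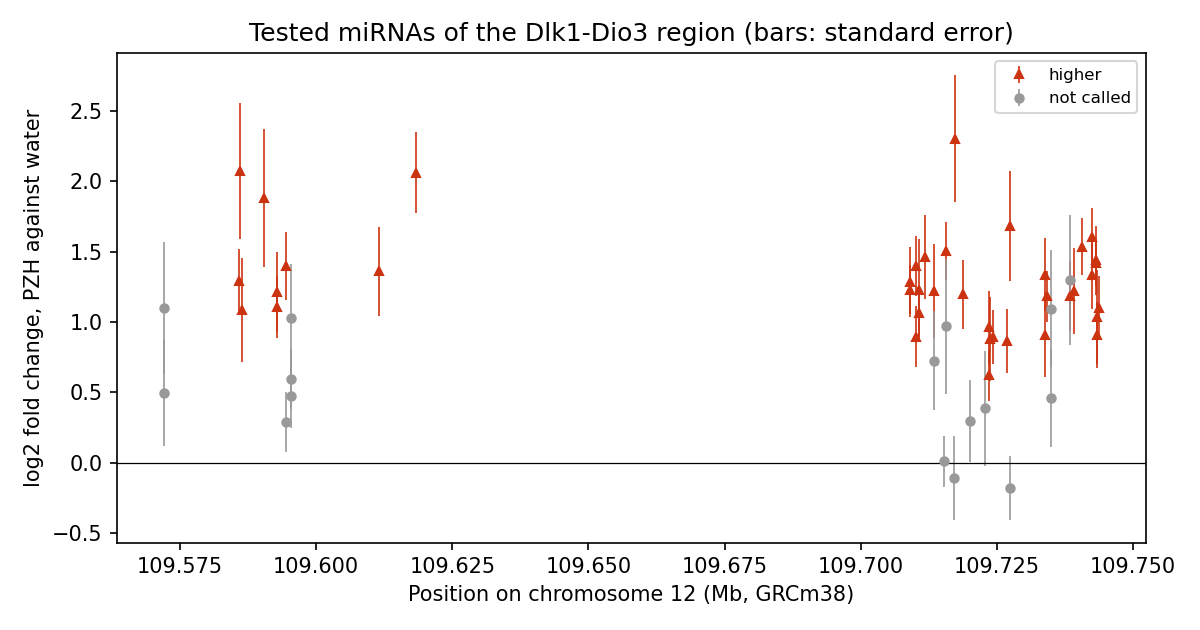
Log2 fold change (PZH against water, with SE) of tested miRNAs along chromosome 12 from position 109571990 to 109743795 of GRCm38, with 1 point per miRNA. Of 55 miRNAs, 39 were called higher.

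The 4 largest decreases at a mean of at least 10 CPM were of miRNAs named without an arm. Of these, miR-6356 fell from 342 ± 167 to 21.0 ± 10.7 CPM (SD, n = 6; log2 fold change -4.04, SE 0.39, edgeR adjusted p = 6.93e-06), from a hairpin on chromosome 18 at 68739400 to 68739501 for which no host gene on the same strand was found. The level of miR-2137, from an intron of Zfp185 on chromosome X at 72992079 to 72992144, fell from 221 ± 52.6 to 26.6 ± 9.64 CPM (SD, n = 6; log2 fold change -3.05, SE 0.22, edgeR adjusted p = 3.02e-07). From an intron of Rfx1 on chromosome 8, miR-709 fell from 143 ± 26.6 to 39.5 ± 15.4 CPM (SD, n = 6; log2 fold change -1.86, edgeR adjusted p = 2.16e-05). The level of miR-6481, whose hairpin shares a run of at least 18 nt with a mitochondrial transfer RNA, fell from 23.2 ± 9.17 to 2.03 ± 1.53 CPM (SD, n = 6; log2 fold change -3.52, edgeR adjusted p = 1.78e-05). Each of these was lower in 6 of 6 PZH mice than in every water mouse.

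Also among the 12 largest decreases were miR-5112 (log2 fold change -1.70), miR-5126 (-0.98), miR-200c-3p (-0.97), miR-141-3p (-0.87), miR-3535 (-0.86), miR-503-5p (-0.85), miR-21a-3p (-0.80) and miR-335-5p (-0.77). Of these miR-503-5p, which restrains cyclins and lies on chromosome X at 53053984 to 53054054, had a narrow spread, with 121 ± 10.3 against 66.8 ± 5.33 CPM (SD, n = 6). Water replicate 2 alone held 235 CPM of miR-5112, 189 CPM of miR-200c-3p and 299 CPM of miR-141-3p, against 70.9, 72.8 and 126 CPM in the next water library. Without it the log2 fold changes were -1.04, -0.53 and -0.48, and the call of miR-141-3p ended (edgeR adjusted p = 0.0831; range over all alternatives 0.00206 to 0.104). That call ended when any 1 of 9 libraries was left out, and the call of miR-200c-3p without PZH replicate 1, 2, 3 or 5 (-0.98 to -0.86).

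Among the 10 most abundant miRNAs, only miR-30a-5p was called by edgeR. It fell from 35172 ± 1473 to 28352 ± 3341 CPM (SD, n = 6; log2 fold change -0.31, edgeR adjusted p = 0.00769), a call that ended without a filter on low counts (adjusted p = 0.0634; range over all alternatives 0.00323 to 0.0634). The others, with no call, were miR-21a-5p (log2 fold change -0.01), miR-122-5p (0.05), miR-143-3p (-0.02), miR-192-5p (-0.20), miR-99a-5p (0.10), miR-194-5p (-0.14), miR-26a-5p (-0.06), miR-148a-3p (0.00) and miR-22-3p (-0.19).

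**Figure D4:**
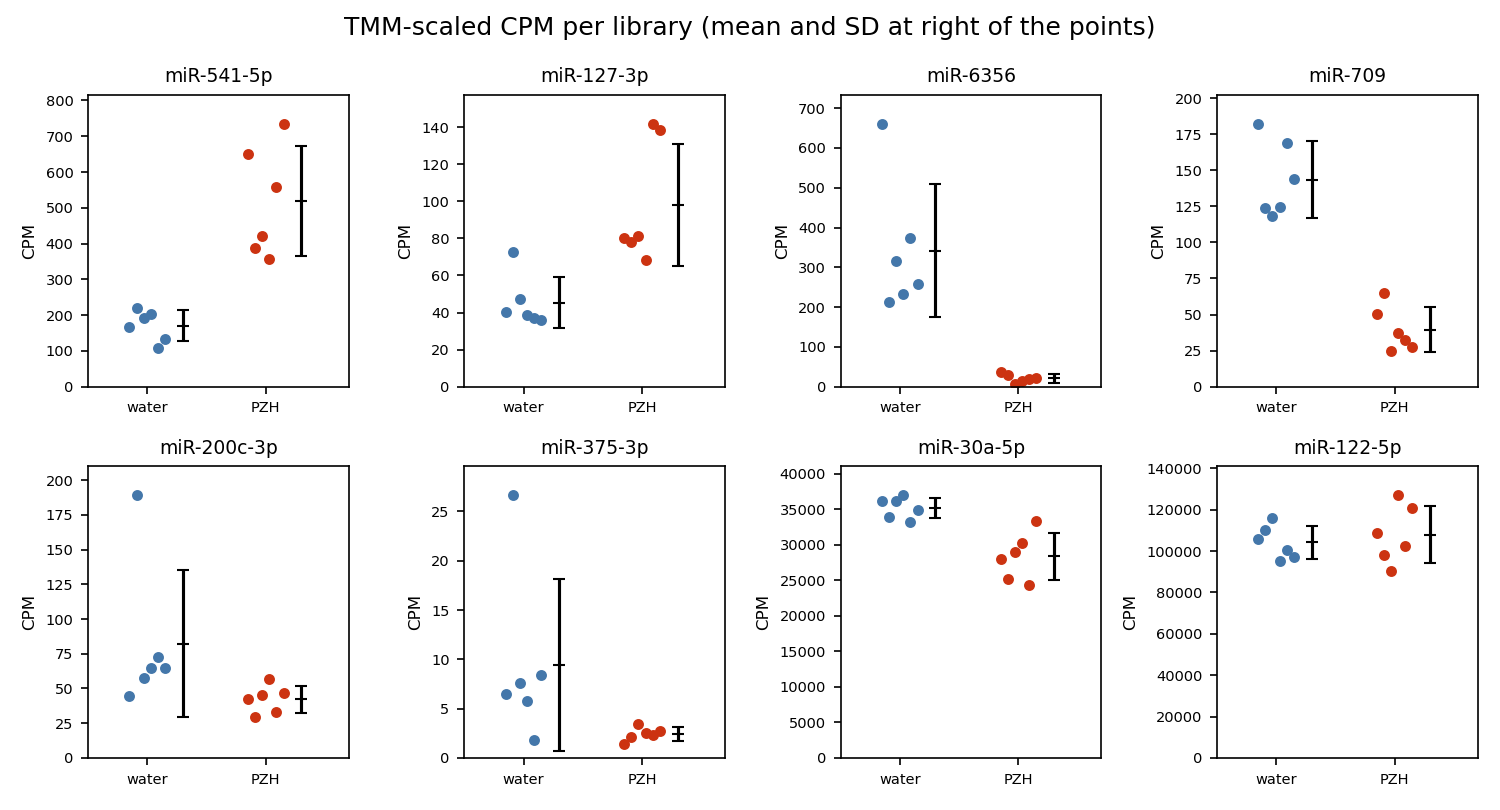
TMM-scaled CPM of 8 miRNAs in each of the 12 libraries, on axes that start at 0, with 1 point per mouse and the group mean ± SD beside the points (n = 6 each). The level of miR-541-5p was higher, and those of miR-6356 and miR-709 lower, in each of 6 PZH mice than in all 6 water mice.

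Of 20 tested miRNAs reported to restrain fibrosis, 10 fell with PZH (11 fell and 1 rose when adjusted over the list alone), with a median log2 fold change of -0.25 over all 20, of which 4 were positive. By camera the list was lower than other miRNAs (adjusted p = 0.00789), a call not kept with the other correlation (adjusted p = 0.515 with an estimated correlation), and by fry it moved down (adjusted p = 0.00372). Those that fell were miR-29c-3p (-0.40), miR-29a-3p (-0.21) and miR-29b-3p (-0.32), which repress collagen messages, miR-30a-5p (-0.31), miR-30e-5p (-0.28), miR-335-5p (-0.77), miR-378a-3p (-0.33), miR-101a-3p (-0.30), miR-200c-3p (-0.97) and miR-146a-5p (-0.47), a regulator of inflammatory signalling. The level of miR-29c-3p went from 366 ± 28.7 to 278 ± 30.6 CPM (SD, n = 6), lower in 6 of 6 PZH mice than in every water mouse. DESeq2 called 6 lower and 1 higher, without miR-29a-3p, miR-29b-3p, miR-30e-5p and miR-101a-3p, and limma-voom called 9 lower, without miR-200c-3p. Without a filter on low counts the call of miR-378a-3p ended, as did that of miR-30a-5p (range of adjusted p for miR-378a-3p over all alternatives 0.001 to 0.0519). The call of miR-146a-5p ended without water replicate 4 (log2 fold change -0.40, edgeR adjusted p = 0.0504), and water replicate 2 was low in miR-335-5p, at 732 CPM against 1186 in the next.

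The fibrosis-promoting list showed no shift in 1 direction (median log2 fold change -0.01, camera adjusted p = 0.879). The mixed form of fry, which takes changes in either direction, gave an adjusted p of 0.0208. Of its 20 tested members miR-221-3p rose (0.34) and miR-21a-3p fell (-0.80), the same counts as when adjusted over the list alone, while miR-21a-5p stood at -0.01. The call of miR-221-3p ended with a block for the replicate number.

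Of 16 tested hepatocyte miRNAs, 6 fell, with the same count adjusted over the list alone, and 3 of the 16 had positive values (median log2 fold change -0.20). The camera adjusted p was 0.0197, lost with the other correlation (adjusted p = 0.515 with an estimated correlation), without PZH replicate 2 (0.0643) and without PZH replicate 3 (0.0607). Those that fell were miR-802-5p (-0.65), from 2583 ± 573 to 1645 ± 409 CPM (SD, n = 6), miR-455-3p (-0.53), miR-455-5p (-0.48), miR-193a-3p (-0.48), miR-101a-3p (-0.30) and miR-101b-3p (-0.26). The members among the 10 most abundant miRNAs were not called, namely miR-122-5p (0.05), miR-148a-3p (0.00), miR-192-5p (-0.20) and miR-194-5p (-0.14). DESeq2 called 4 lower, without miR-101a-3p and miR-101b-3p. Without a filter on low counts the calls of miR-101b-3p and miR-455-5p ended (ranges of adjusted p over all alternatives 0.00725 to 0.185 and 0.00511 to 0.0527). By fry the list moved down (adjusted p = 0.00372).

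In exact permutation tests of the mean log2 CPM of a list, chosen after the values were seen, the Dlk1-Dio3, fibrosis-restraining and hepatocyte lists each gave p = 0.00216, the smallest possible, with an adjusted p of 0.0101 over 14 lists. The mean of the Dlk1-Dio3 list was higher in 6 of 6 PZH mice than in every water mouse, with a difference of 1.08 on the log2 scale. The means of the other 2 lists were lower in 6 of 6, with differences of -0.25 and -0.24.

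**Figure D5:**
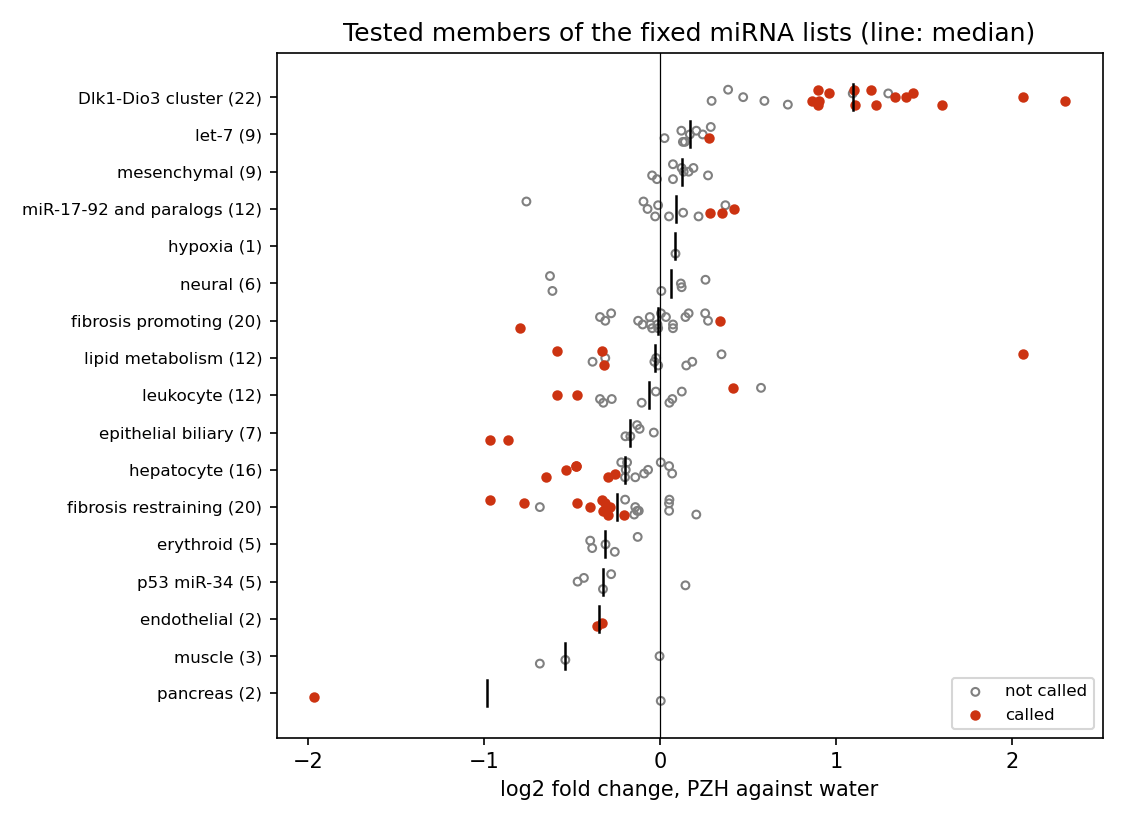
Log2 fold change (PZH against water) of each tested member of the fixed lists, with 1 point per miRNA, called ones in colour and the list median as a line. The median was 1.10 for the Dlk1-Dio3 list, -0.25 for the fibrosis-restraining list and -0.20 for the hepatocyte list.

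Members of the let-7 family, which restrain growth, had a median log2 fold change of 0.17 over 9 tested miRNAs, all positive under each scaling tried. Of them let-7b-5p rose (0.28), and none was called when adjusted over the list alone, while DESeq2 called 3. The camera adjusted p of 0.0275 was lost with the other correlation (adjusted p = 0.728 with an estimated correlation), with fry (adjusted p = 0.0853), and without water replicate 1 (0.0887), PZH replicate 2 (0.0643) or PZH replicate 4 (0.077). The call of let-7b-5p ended in 13 of 24 alternatives, which were 9 libraries left out in turn, no filter, robust edgeR, limma-voom with quality weights and the replicate block. Of the growth-promoting miR-17-92 cluster and its paralogs, 3 of 12 tested members rose, namely miR-17-5p (0.42), miR-93-5p (0.35) and miR-20a-5p (0.28), and 4 when adjusted over the list alone. The list's median was 0.09 (camera adjusted p = 0.149; fry adjusted p = 0.0300), and the call of miR-20a-5p ended when any 1 of 6 libraries was left out, without a filter and with the replicate block.

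The endothelial list held the arms of a single hairpin. The level of miR-126a-3p, which lies within the endothelial gene Egfl7, fell from 10223 ± 665 to 7974 ± 760 CPM (SD, n = 6; log2 fold change -0.36, edgeR adjusted p = 0.00281), in 6 of 6 PZH mice below every water mouse. Its partner arm miR-126a-5p fell too (-0.33, edgeR adjusted p = 0.0445), a call that ended in 17 of 24 alternatives, among them DESeq2, limma-voom, RLE and total-count scaling and the omission of any 1 of 9 libraries (range of adjusted p 0.00361 to 0.117). Water replicate 2 was low in it, at 3735 CPM. With 2 members this list had no set test. Mesenchymal miRNAs, which mark stellate cells and fibroblasts, gave no call among 9 tested members (median 0.12, camera adjusted p = 0.502). In the leukocyte list 2 of 12 fell and 1 rose, with the same counts adjusted over the list alone (median -0.06, camera adjusted p = 0.717, mixed fry adjusted p = 0.000476). These were the myeloid miR-223-3p (-0.58; 943 ± 119 to 629 ± 141 CPM; SD, n = 6), miR-146a-5p (-0.47) and the lymphoid miR-342-3p (0.42).

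The epithelial and biliary list had 2 of 7 tested members fallen, miR-200c-3p and miR-141-3p, both highest in water replicate 2 as given above (median -0.17, camera adjusted p = 0.502). Both calls also ended with limma-voom, without and with quality weights, and with a block for the replicate number, so that limma-voom called 0 of the 7 and DESeq2 2. Erythroid miRNAs gave no call among 5 tested (median -0.31, camera adjusted p = 0.267). Muscle miRNAs gave none among 3 (median -0.54, camera adjusted p = 0.857), and those of p53 and miR-34 none among 5 (median -0.32, camera adjusted p = 0.502). Neural miRNAs gave none among 6, with a median of 0.06, a mean of -0.12 and a camera direction of down (adjusted p = 0.879). In lipid metabolism, miR-370-3p rose and miR-223-3p, miR-378a-3p and miR-378a-5p fell out of 12 tested members, with the same counts adjusted over the list alone. That list had a median of -0.03, a mean of 0.06 and a camera direction of down (adjusted p = 0.879, mixed fry adjusted p = 1.80e-05), and DESeq2 and limma-voom each called 2 lower. The call of miR-378a-5p ended in 17 of 24 alternatives, among them DESeq2, limma-voom, RLE and total-count scaling, the block for the replicate number and the omission of any 1 of 9 libraries (range of adjusted p 0.0135 to 0.194). Of the lists with no call by edgeR (mesenchymal, erythroid, muscle, neural, and p53 and miR-34), DESeq2 and limma-voom also called 0 members, while at an unadjusted p under 0.05 the mesenchymal list had 1 higher member and the erythroid, neural and p53 lists 1 lower each. The hypoxia miRNA miR-210-3p stood at 0.09. Of the pancreas list, miR-375-3p fell from 9.44 ± 8.72 to 2.42 ± 0.673 CPM (SD, n = 6; log2 fold change -1.97, edgeR adjusted p = 0.00769; -1.27 without water replicate 2), and miR-148a-3p stood at 0.00. The call of miR-375-3p ended with limma-voom, without and with quality weights (adjusted p = 0.0808 and 0.141; range over all alternatives 3.29e-05 to 0.141).

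The balance between the arms of hairpins asks a question that library scaling does not touch. For miR-335, from an intron of the imprinted gene Mest, the 5p arm fell (log2 fold change -0.77) while the 3p arm rose (0.44). The log2 ratio of 5p to 3p was 2.69 ± 0.488 with water and 1.48 ± 0.201 with PZH (SD, n = 6; difference -1.21, limma adjusted p = 0.00496). Of 137 hairpins tested, 8 ratios were higher and 3 lower with PZH, and 38 passed an unadjusted p under 0.05. The lower ones were those of miR-335, miR-503 (-0.67) and miR-221 (-0.39). The higher ones were those of miR-434 (1.15), miR-193a (1.11), miR-877 (0.98), miR-21a (0.78), let-7e (0.75), miR-671 (0.63), miR-744 (0.52) and miR-17 (0.40). In miR-21a the 3p arm fell and the 5p arm stood at -0.01. The count of 11 dropped to 3 without water replicate 1 or 4, to 4 without water replicate 3 or PZH replicate 6, and to 5 without water replicate 5, PZH replicate 1 or PZH replicate 5. The ratios of miR-335, miR-503 and miR-434 kept their calls in each of the 12 fits that left out 1 library.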

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

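All tests of explanations in this part were chosen after the result was seen. For each named miRNA and composition measure, the gap of the most distant library was divided by the range of its group of 6, and a library was taken as far from the others where this ratio passed the critical value of Dixon's test, which chance reaches in about 1 of 20 groups. For miRNAs the ratio was taken on log2 CPM, while the levels given below are CPM. Of 172 groups 18 passed, and 14 of them were in water replicate 2, the library with the largest total.

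Water replicate 2 was the highest water library in the percent of counts in the 10 most abundant miRNAs (63.0% against 60.9% in the next; ratio 0.638), miR-379-5p (95.7 against 64.2 CPM; 0.721), miR-5112 (235 against 70.9 CPM; 0.699), miR-200c-3p (189 against 72.8 CPM; 0.663), miR-141-3p (299 against 126 CPM; 0.645) and miR-200a-3p (996 against 639 CPM; 0.657). It was also the highest in miR-429-3p (85.4 against 47.9 CPM; 0.627), miR-1a-3p (71.6 against 19.9 CPM; 0.703), miR-218-5p (32.5 against 20.02 CPM; 0.713) and miR-145a-3p (1791 against 1458 CPM; 0.68). It was the lowest in miR-335-5p (732 against 1186 CPM; 0.764), miR-22-3p (16678 against 22098 CPM; 0.733), miR-126a-5p (3735 against 5254 CPM; 0.714) and miR-144-5p (92.1 against 141 CPM; 0.631).

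In water replicate 2, 11 miRNAs with a mean of at least 10 CPM lay over 1.5-fold above every other water library, against 1, 2, 0, 0 and 0 in water replicates 1, 3, 4, 5 and 6. Exocrine pancreas is argued against, because 4 miRNAs of acinar cells summed to 2.37 CPM in this library, where miR-375-3p stood at 25.3 CPM, both without TMM scaling. Epithelium and muscle of a neighbouring tissue may be a source, since the epithelial list had a median log2 ratio of 1.26 to the mean of the other water libraries and the muscle list 2.23, while hepatocyte miRNAs stood at -0.05. This cannot be told apart from a difference between mice, because the idea came from these values and the muscle list has 3 tested members. Both tests concern tissue taken with the sample, no difference in biology between this mouse and the others was tested, and without this library edgeR called 139 miRNAs, 60 higher and 79 lower.

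The other values far from their group were miR-21a-3p, low in PZH replicate 1 (71.9 against 117 CPM in the next; ratio 0.747), and miR-155-5p, high in water replicate 4 (292 against 223 CPM; 0.663). A low value was also found for miR-145a-5p in water replicate 1 (3461 against 4013 CPM; 0.646) and for miR-499-5p in water replicate 4 (0.553 against 1.24 CPM; 0.694).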

How the results depend on the processing

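Thinning, with and without libraries left out, and the omission of names without an arm were chosen after the data were seen. Across 2592 recomputed values no called value reversed, and 66 uncalled values changed sign. The total of 129 calls lay between 94 and 144 under other scalings, filters and tools, and between 99 and 139 with 1 library left out. With a block for the replicate number it was 114, of which 104 were among the 129. Other scalings moved the median of all tested miRNAs by less than 0.1 on the log2 scale.

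With the filter of 10 CPM in 6 libraries, which tests fewer miRNAs, 35 were lower. After thinning, which lowers counts, 45 were lower. With an absolute log2 fold change of at least 1, there were 58 calls, 35 higher and 23 lower. The 4 list calls dropped to 0 with an estimated correlation (Dlk1-Dio3 at an unadjusted p of 0.0354). The fry test called 3 of those 4 lists and, in place of let-7, miR-17-92. The list calls dropped to 2 without a filter (the cause was not tested), and lay between 2 and 4 with 1 library left out: 2 without PZH replicate 2, and 3 without water replicate 1, PZH replicate 3 or PZH replicate 4. The difference in detected miRNAs lay between -203 (without water replicate 6) and -94.8 (without water replicate 2), and after thinning, which corrected for depth only in part, was -132 without water replicate 6. The 11 arm ratios became 19 with at least 100 counts, 6 with the replicate block, and 3 to 14 with 1 library left out; the cause was not tested. Separation with the block was 56.3% (exact permutation p = 0.0312, the smallest it can give).

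Of named miRNAs, 1814 values kept their side of the threshold, 89 lost a call and 43 gained one. Calls ended with 1 library left out for let-7b-5p (water 1, 2, 3, 4, 6, PZH 2, 4, 5, 6; 0.21 to 0.30), miR-126a-5p (water 1, 3, 4, 5, 6, PZH 1, 2, 3, 5; -0.35 to -0.28), miR-378a-5p (water 1, 3, 5, 6, PZH 1, 2, 3, 5, 6; -0.33 to -0.28), miR-141-3p (water 2, 4, 5, 6, PZH 1, 2, 3, 5, 6; -0.93 to -0.48), miR-20a-5p (water 1, 3, 4, PZH 3, 5, 6; 0.24 to 0.30) and miR-101b-3p (water 4, PZH 2, 5; -0.23 to -0.22). Calls also ended for miR-200c-3p without PZH 1, 2, 3 or 5 (-0.98 to -0.86) and for miR-146a-5p without water 4 (-0.40). On simulated data 20.8% of the smallest changes tried were recovered, so small changes remain undetected at this depth and number of mice.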

Other observations

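The tests in this part, apart from the counts over splits of the libraries, were chosen after the results were seen, as were the miRNAs named here. Of 60 miRNAs higher with PZH, 65% came from the Dlk1-Dio3 region, where 39 of 55 tested miRNAs from 39 hairpins were higher and 0 lower by edgeR (45 and 0 at an unadjusted p under 0.05, 42 and 0 by DESeq2, 37 and 0 by limma-voom). Outside it, 21 of 552 were higher (3.80%), with a median log2 fold change of 0.42 (Fisher's exact p = 2.66e-33, in which neighbouring miRNAs are treated as independent). Other imprinted loci held fewer tested miRNAs, and the difference from this region was not tested. In introns of Sfmbt2, miR-466p-3p, miR-466d-3p and miR-669o-3p (0.80) rose and miR-466m-3p fell (-1.42) out of 14 tested miRNAs, a family of near-identical copies. At Nespas, miR-296-3p rose (1.09) and miR-296-5p stood at 0.14, and at Mest, as given above, 1 arm of miR-335 rose and 1 fell.

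Some miRNAs of low abundance were lower with PZH. The level of miR-7056-3p went from 9.83 to 0.346 CPM, and that of miR-293-5p, of a cluster of embryonic stem cells, fell by 3.97 on the log2 scale. The level of miR-327 went from 12.4 to 1.59 CPM. Falls were also found for miR-490-3p (-1.81) and miR-135a-5p (-1.57). At the Egfl7 locus all 4 tested miRNAs of miR-126a and miR-126b were lower, but they lie on opposite strands and the use of strand in counting is not given in the sources used here.

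Chance can be excluded for the number of miRNAs called, since 1 of 100 splits of the 12 libraries into 6 and 6, the real one, gave as many as 129, and the highest other gave 62. Chance is likewise unlikely but not excluded for the number of arm ratios, where 2 of 100 splits, the real one included, gave 11 or more. The highest other gave 11, the same count as the real one. Chance cannot be excluded for the number of lists called by camera, where 31 of 100 splits gave 4 or more and the highest other gave 8.

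For the higher Dlk1-Dio3 miRNAs, with a list median of 1.10, the tested miRNAs outside the region had a median of -0.0601 (SD 0.61). TMM scaling holds the bulk of the miRNAs near 0, so this median by itself cannot test library scaling. The values show a rise relative to the other miRNAs, and absolute amounts were not measured. A larger share of mesenchymal cells as a whole is argued against by that list's median of 0.12, with members between -0.05 and 0.27. Under total-count scaling all 9 tested members of that list were positive. A rise in only some of these cells was not tested. A drift with abundance is argued against because the list median lay at percentile 100 of 10000 random lists matched on expression, whose highest median was 0.29. A higher level of the host non-coding RNAs with PZH may be a source, a hypothesis not tested here because these RNAs were not measured, and against a rise shared by every miRNA of the region miR-494-3p stood at 0.01 (SE 0.18, mean 123 CPM), with miR-487b-5p at -0.18 and miR-666-5p at -0.11. A difference in handling between the groups stays open, since no labels give a batch.

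Of 72 tested miRNAs named without an arm, 16 were lower and 0 higher by edgeR (21 and 2 at an unadjusted p under 0.05, 16 and 1 by DESeq2, 16 and 0 by limma-voom). That is 22.2% lower against 9.91% of the 535 others (Fisher's exact p = 0.00465). This p treats miRNAs as independent. It counts the 4 largest decreases given above and miR-5112, miR-5126 and miR-3535, also named without an arm, all seen before. The 16, selected for being lower, had a median log2 fold change of -1.24 against -0.09 over all 72. The difference in depth is argued against as the whole cause. Of miRNAs named without an arm, 18 were selected as lower in PZH replicates 1, 3 and 5 against the 3 deeper water libraries (median log2 difference -1.44). The libraries left out of the selection were PZH replicates 2, 4 and 6 and the 3 shallower water libraries. There the median of PZH against water was -0.95, with 17 of 18 negative. Of the 18, 15 were among the 16 called in all 12 libraries, so the direction was in part known beforehand. Fragments of small nuclear, nucleolar, Cajal body or mitochondrial RNAs are argued against as the whole cause, because 2 of 15 searched hairpins share a run of at least 18 nt with one. For those miRNAs, miR-6481 and miR-5121 (median -2.35), such fragments cannot be told apart from a change in the miRNA, as they are too few. Fragments of ribosomal RNA and cytoplasmic transfer RNA were not searched and may contribute, and an effect of PZH stays open.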
